A study of Mus musculus with 4 samples.

How the data were processed

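CD4 T cells from the lungs of C57BL/6 mice were profiled by droplet-based single-cell sequencing in 2 tissues, lung bearing TC1 tumors 3 weeks after tumor cells were given by tail vein and normal lung of age-matched mice. Per the labels' protocols, lungs were perfused, minced and digested with collagenase, lymphocytes were enriched on a Percoll gradient and by magnetic selection, and live CD4-positive cells were sorted by flow cytometry. Each suspension gave a 5' gene expression library and a T cell receptor (TCR) library. The labels do not say how many mice went into a suspension. The protocol aimed at 10000 cells per library.

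The deposited gene expression values were raw UMI counts per gene and cell barcode, that is, counts of distinct molecules. Per the submitters' processing notes they came from Cell Ranger on the mm10 genome, and per the file headers the software version was 3.1.0. The barcodes had already been reduced to those called cells, 7788 in the tumor library and 7745 in the normal library. The deposited TCR tables gave for each assembled contig its chain, V and J genes, CDR3 sequence, UMI count and read count per the file headers, with 22605 contigs from 7257 barcodes in the tumor library and 22474 contigs from 7432 barcodes in the normal library. The version of the receptor assembler and its reference were not given in the sources used here. Of 31053 gene identifiers, 30934 were found in a table of mouse gene names for assembly GRCm38.p6, which also supplied the coordinates printed here.

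Cells with fewer than 500 detected genes or 10% or more mitochondrial UMIs were left out, 120 in the tumor library and 61 in the normal library. Scrublet as implemented in scanpy, with an expected doublet rate of 6%, called 4 and 1 cells, too few for the caller to have worked. Doublets were therefore removed mainly through the receptors, and cells with more than 2 productive alpha or more than 1 productive beta chain were left out, 533 in the tumor library and 602 in the normal library. Analysis kept 7133 tumor and 7081 normal cells. Both libraries were clustered together on 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1. T cell receptor and immunoglobulin segments, ribosomal protein genes and mitochondrially encoded genes were left out of the variable genes.

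A cluster was named from a marker list when at least 2 of its 10 leading genes by fold were markers of that type and at least 3 of the type's markers were detected. Naive-like clusters were those without such markers that exceeded the named clusters in most of the naive markers, which include Ccr7, Lef1, Tcf7, S1pr1 and Klf2. Clusters 0 and 10 were Treg-like. Cluster 0 was led by Tnfrsf9, Plac8, Mt1, Gzmb, Fgl2, Foxp3, Cd83, Klrg1, Areg and Il2ra and is called activated here, and cluster 10 was led by Lrrc32, Gpr83, Foxp3 and Mbnl3 and is called resting. Cluster 9 was Th1 or cytotoxic-like, with Ccl5, Nkg7, Ifng, Ly6c2 and Cxcr6 among its leading genes beside the Th17 markers Tmem176a and Tmem176b. Clusters 5 and 8 were interferon-responding, clusters 1, 2, 3, 4, 6 and 7 were naive-like, and cluster 11 stayed unnamed, since it had fewer than 2 markers of any type among its leading genes and exceeded the named clusters in 4 of 12 naive markers, where 8 were needed. Since interferon genes define clusters 5 and 8 and differ between the libraries, their sizes were not compared. The classes are rebuilt from the counts and are not the authors' annotation.

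Raw UMI counts were summed per library and class and expressed as CPM, the count scaled to a fixed total of that sum. Intervals are 95% intervals, exact Poisson for a CPM, exact conditional on the total for a ratio, and Clopper-Pearson for a share of cells. A share of 0 is given instead with the limit that 3 counts of its total allow. With 1 library per group there was no test, no p-value and no replicate check, and any batch difference between the libraries cannot be told apart from the tissue difference. Intervals and floors cover counting error only. Cells of 1 clone are not independent, but the intervals for shares of expanded cells and of V genes over cells treat them as if they were. Likewise UMIs of 1 cell are not independent, but the intervals for a CPM or a ratio treat them as if they were. A library at 0 UMIs was set to a floor of 3 counts. Scaling by median of ratios instead of by total counts shifts Treg-like log2 ratios by -0.11, and the median log2 ratio over all expressed genes in that class was 0.16. For shares of cells with a UMI, each cell was also thinned to 2417 UMIs, the 10th percentile of the shallower library, and shallower cells were left out.

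Genes named in each tissue comparison were the 10 with the largest and the 10 with the smallest ratio among genes with at least 100 UMIs in the higher library, without receptor and immunoglobulin segments, mitochondrial, ribosomal protein, hemoglobin and sex-linked marker genes, and 24 preset genes such as Foxp3, Il1rl1 and Pdcd1, of which 1 is not reported here. For Il1rl1-positive against Il1rl1-negative Treg-like cells they were the 10 highest and 5 lowest genes by the smaller change of both libraries, with at least 20 UMIs. Gene lists covered tissue Treg and IL-33 response genes, Treg effector molecules, TNF receptor family, inhibitory receptors, IL-1 family and NF-kB signalling, IL-2 and STAT5 signalling, naive and lymph node homing, chemokine receptors and tissue retention, Th1 and cytotoxic, Th17, Th2, Tfh, interferon response, MHC class I, proliferation, glycolysis, hypoxia, TGF-beta response, immediate early genes, heat shock and mitochondrially encoded genes, as well as lung epithelium, myeloid, B cell and erythroid background and a sex check. A list member counted as measured with at least 10 UMIs in the sums, and as higher or lower at a ratio of at least 1.5. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Members at 0 UMIs in a library enter that median at their floor.

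A TCR clonotype was a set of cells with identical productive alpha and beta CDR3 nucleotides and V genes, among cells with 1 or 2 alpha chains and 1 beta chain. Diversity was averaged over 1000 draws of equal numbers of cells, and sharing between classes was set beside 1000 shuffles of the class labels.

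The groups, comparisons, gene lists, markers and naming rule, and most alternatives, were fixed before the data were examined. Alternatives were stricter and absent cell filters, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered on its own, Treg-like cells taken as cells with a Foxp3 UMI, median of ratios scaling, thinning before summing, the mean over cells, other UMI minimums, cells of the cluster named proliferating at resolution 2 left out, and other clonotype definitions. Added after seeing the data were removal of cells with the top 5% of doublet scores, clustering without 977 genes that differed at least 2-fold between the libraries, values within cluster 0 alone, non-Treg cells without clusters 5 and 8, receptor results without cells under the thinning depth or without naive-like cells or in equal draws of cells, TRBV26 and expansion of Th1 or cytotoxic-like cells without the largest clone, and lists in Treg-like cells without the leading genes of clusters 0 and 10 and the Treg markers. On simulated counts for the Treg-like comparison over 10801 genes, the interval lay on the right side for 99 of 100 genes changed 2-fold and 100 of 100 genes changed 4-fold, and held the true ratio for 96.7% of genes. For the non-Treg comparison over 12537 genes the figures were 100 of 100, 100 of 100 and 96.1%. These counts were drawn as Poisson, the model behind the intervals, without extra spread between cells or libraries. They check the calculation and not how well the intervals hold for real counts. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.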

Results

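Sorted CD4 T cells from mouse lung carrying TC1 tumors, a transplantable line derived from mouse lung epithelium, and from normal lung were each represented by 1 gene expression library and 1 TCR library. The tumor gene expression library held 35633167 UMIs in 7788 barcodes with a median of 4210 per barcode, and the normal library held 31697386 UMIs in 7745 barcodes with a median of 3949. The cells kept held 31901322 and 28079348 UMIs, with median depths of 4173 and 3906 UMIs and medians of 1533 and 1424 detected genes. The TCR libraries held 131798 and 127035 contig UMIs. A paired alpha-beta receptor was assigned to 5705 of the 7133 kept tumor cells (80.0%, 79.0 to 80.9) and to 5459 of the 7081 kept normal cells (77.1%, 76.1 to 78.1). There was 1 library per tissue, so each difference below is between libraries and has no replicate check.

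The first comparison asked whether regulatory T cells (Tregs), the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3, make up a larger share of lung CD4 T cells when tumors are present. Treg-like cells were 1225 of 7133 in the tumor library (17.2%, 16.3 to 18.1) and 249 of 7081 in the normal library (3.52%, 3.1 to 3.97), a 4.88-fold higher share. Naive-like cells were lower in the tumor library, 4458 cells (62.5%, 61.4 to 63.6) against 5956 cells (84.1%, 83.2 to 85.0). Th1 or cytotoxic-like cells, named for leading genes such as Ccl5, Nkg7 and Ifng, made up 771 cells (10.8%, 10.1 to 11.6) against 684 cells (9.66%, 8.98 to 10.4), with overlapping intervals. A UMI of the protease gene Gzma was seen in only 18 and 55 of these cells, and under 4 alternatives most of the class was named Th17-like, with 1399 cells against 113 Th1 or cytotoxic-like ones without a cell filter. The remaining 621 and 184 cells were interferon-responding and 58 and 8 were unnamed.

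**Figure D1:**
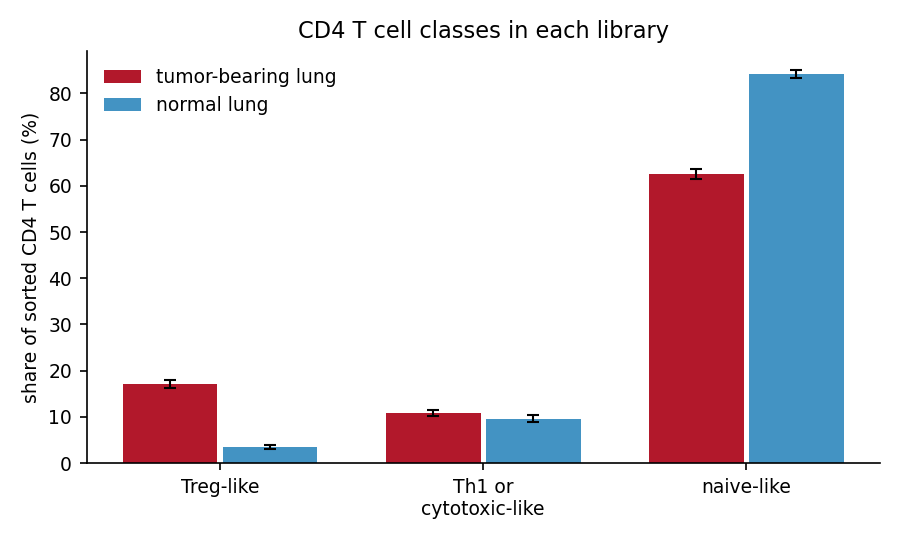
Share of sorted CD4 T cells (percent) in 3 classes for the tumor library and the normal library, with bars for the measured share and error bars for the exact binomial 95% interval. Treg-like cells took 17.2% of the tumor library and 3.52% of the normal library.

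Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243, GRCm38.p6) gave the same direction without any clustering. A Foxp3 UMI was found in 1145 tumor cells (16.1%) and 206 normal cells (2.91%), and after thinning, which left out 393 and 708 cells, in 13.1% and 2.43%. Naive-like cells, which should lack the gene, gave 1.05% and 0.604% at median depths of 4099 and 3891 UMIs, or 0.515% and 0.392% thinned. The 2 Treg-like clusters were filled differently. Activated cluster 0 held 1081 tumor cells, 88.2% of the tumor library's Treg-like cells, and 65 normal cells (26.1%), while resting cluster 10 held 144 (11.8%) and 184 (73.9%). A cluster so dominated by 1 library may in part be that library, and when genes that differed between the libraries were left out of the clustering the corresponding numbers were 1115 and 118 tumor cells against 63 and 158 normal cells. Naive-like cells also lay in different clusters, with clusters 1 and 3 holding 56.6% and 18.3% of those in the tumor library and clusters 2, 6, 4 and 7 holding 38.6%, 27.2%, 19.5% and 10.0% of those in the normal library.

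Within Treg-like cells, the tumor library had more transcripts of Ccl5, Ctla2a and Ctla2b, 20 of 21 interferon response genes were at least 1.5-fold higher there, and 11 of 12 naive and lymph node homing genes were lower. Ccl5, a chemokine, was 35.1-fold higher (21.6 to 61.5, 3489 against 16 UMIs), Ctla2a, which encodes a cysteine protease inhibitor, 28.9-fold higher (19.7 to 44.2), and its neighbour Ctla2b 62.0-fold higher (11.1 to 2456, 1 UMI in the normal library). The interferon-induced Ifit3 was 55.7-fold higher (19.0 to 270.5, 3 UMIs in the normal library). Klf2, a transcription factor that sustains lymph node homing receptors, was lower in the tumor library, 5.40-fold higher in the normal library (5.04 to 5.80). The depth behind these sums was 6547369 UMIs from tumor Treg-like cells and 1054825 UMIs from normal ones.

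The rule for the largest differences also named, on the side of the tumor library, Cxcl2 at 49.0-fold (8.72 to 1941), AA467197 at 42.8-fold (14.6 to 208), Rapsn at 28.6-fold (12.2 to 88.4), Sv2c at 26.8-fold (13 to 66.7) and Tff1, with 503 UMIs against 0, at least 27.0-fold. Plac8, which is also among the genes that define cluster 0, had 2788 UMIs against 1. On the side of the normal library it named St8sia6 (7.41-fold higher there), Tubb2a (7.40), Ly6c1 (6.36), Evl (4.80), Klf3 (4.80), Pdlim1 (4.78), Rflnb (4.44), Cd7 (4.43) and Gm2682 (4.21).

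Among the preset genes, checkpoint and costimulatory receptors of activated Tregs were higher in tumor Treg-like cells. Pdcd1, which encodes the inhibitory receptor PD-1, was 7.19-fold higher (5.79 to 9.05), Lag3 10.8-fold, Tigit 5.67-fold and Havcr2 21.8-fold (5.99 to 181, 2 UMIs in the normal library). Ctla4, the checkpoint receptor through which Tregs restrain antigen-presenting cells, was 2.45-fold higher, Icos 1.62-fold, Tnfrsf4 2.97-fold and Tnfrsf18 3.07-fold. Ccr8, a chemokine receptor of tissue Tregs, was 11.3-fold higher (8.73 to 15) and Il10, an anti-inflammatory cytokine, 25.7-fold higher (7.06 to 213, 2 UMIs in the normal library). Gata3 was 1.52-fold and Ikzf2 1.75-fold higher. Ifng was 7.89-fold higher with an interval from 1.35 to 318 and 1 UMI in the normal library, and its direction turned under the strict cell filter and at Leiden resolution 2 (log2 ratios of -1.07 and -0.12). Tcf7 and Ccr7, genes of naive and lymph node homing cells, were 3.24-fold and 3.74-fold higher in the normal library. Il17a had 15 UMIs against 0, which this depth cannot tell apart. Foxp3, Il2ra, Tnfrsf9, Klrg1, Areg and Gzmb, at 1.69-fold, 2.59-fold, 8.43-fold, 4.67-fold, 1.71-fold and 16.7-fold, are among the genes that define cluster 0, which holds most tumor Treg-like cells, so these ratios are not read as findings of their own. Ctla4, Tnfrsf4, Tnfrsf18 and Ikzf2 are not leading genes of cluster 0 but are on the Treg marker list used for naming. Within cluster 0 their ratios were 1.73, 2.71, 2.90 and 1.40.

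Because the 2 libraries fill the Treg-like clusters so differently, the same ratios were taken within activated cluster 0 alone, after the first values were seen. Ccl5 was then 27.3-fold higher in the tumor library (13.8 to 63.2), Ctla2a 11.6-fold, Ccr8 6.17-fold, Pdcd1 4.99-fold and Lag3 4.85-fold. Il10 was 9.86-fold higher (2.71 to 81.8, 2 UMIs in the normal library). Klf2 kept a tumor to normal ratio of 0.278. Areg, the tissue-repair growth factor amphiregulin, turned around to a ratio of 0.790 (0.682 to 0.920), as did Icos (0.790), while Tubb2a reached 1.21 (0.646 to 2.57). At Leiden resolution 2 most of the normal library's cluster 0 cells joined a cluster named proliferating, and then 9 of the 20 genes with the largest differences were still among the 20.

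**Figure D2:**
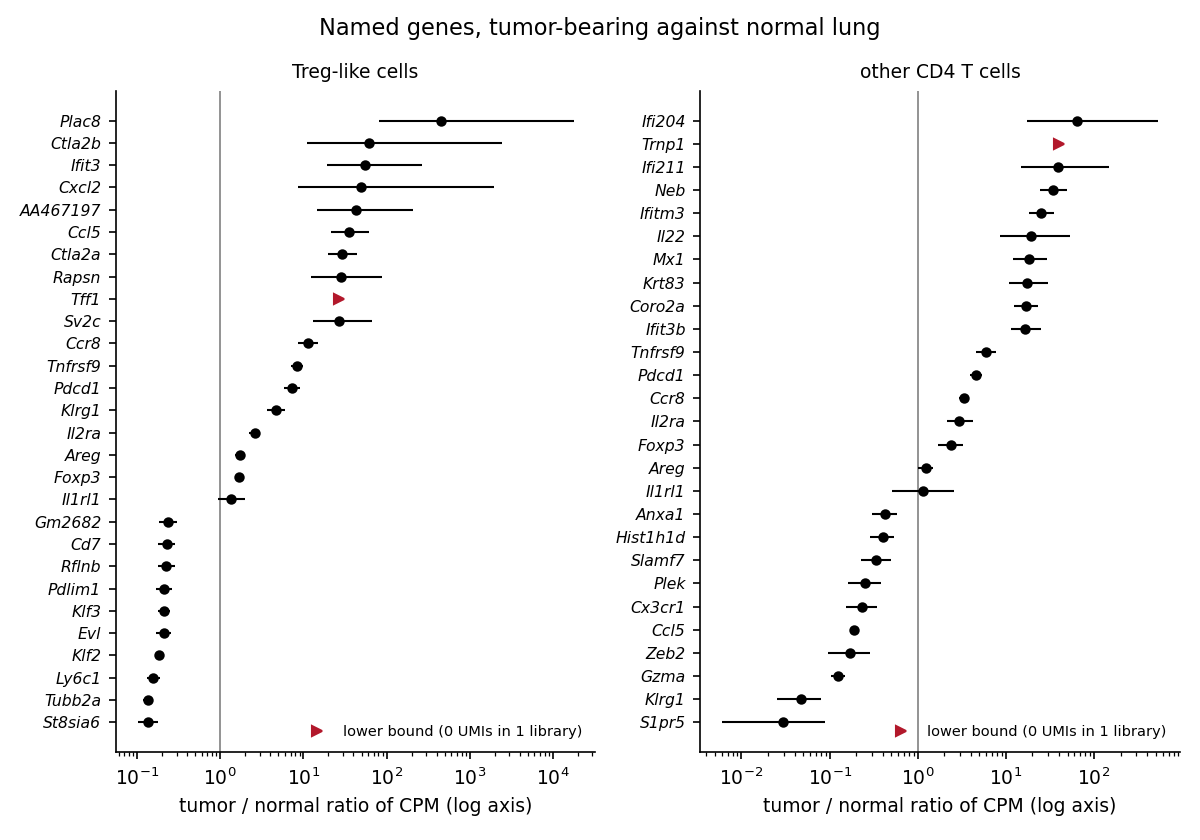
Tumor to normal ratio of CPM (log axis) for the genes named by size and 8 preset genes in Treg-like cells and in the other CD4 T cells, with points for the ratio, lines for the exact 95% interval and triangles for lower bounds. In Treg-like cells Ccl5 lies at 35.1 and Il1rl1 at 1.35.

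Gene groups fixed in advance were then compared in Treg-like cells. Of 18 tissue Treg and IL-33 response genes, 17 were at least 1.5-fold higher in the tumor library and 0 were lower (median log2 ratio 1.14, percentile 100 among random lists), with Il10, Ccr8 and the transcription factors Batf (1.98-fold) and Rora (2.04-fold) as examples. Of 15 Treg effector molecules 13 were higher and 1 lower (1.97, percentile 100), and of 12 inhibitory receptors 9 were higher and 0 lower (1.29, percentile 100). Of 21 interferon response genes 20 were higher (2.20, percentile 100), among them Isg15 (6.56-fold), Irf7 (3.87-fold) and Bst2 (4.61-fold). The Th1 and cytotoxic list had 11 of 13 higher (1.03, percentile 99.8), where 3 genes had 0 normal UMIs and the median is the lower bound of 1 of them, Gzma, with Tbx21, the Th1 transcription factor, at 9.26-fold on 2 normal UMIs. Of 12 naive and lymph node homing genes 11 were lower and Il7r alone was higher (-1.68, percentile 0).

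TNF receptor family genes split, with 7 of 12 higher and 2 lower (0.90), as did chemokine receptors and retention genes, with 10 of 16 higher and 4 lower (1.05). In the latter group Cxcr3 (5.81-fold) and Cxcr6 (9.30-fold), receptors for inflamed tissue, were higher, and Ccr9 (0.204) and Cxcr5 (0.335) had ratios below 1. IL-2 and STAT5 signalling had 7 of 12 higher and 3 lower (0.87), and IL-1 family and NF-kB signalling 7 of 18 higher and 0 lower (0.47, percentile 97.6), led by the decoy receptor gene Il1r2 at 9.77-fold. MHC class I genes had 8 of 12 higher (0.79). Within cluster 0 alone the interferon list kept a median of 2.08 with 21 of 21 higher and the Treg effector list 1.29, the tissue Treg list was at 0.42 with 8 of 18 higher and 1 lower, and the naive list was at -1.05. Inhibitory receptors there were at 0.67 with 6 of 12 higher, and chemokine receptors and retention genes at 0.12 (percentile 75.7) with 6 higher and 6 lower. IL-1 family and NF-kB signalling in cluster 0 was at 0.26 (percentile 93.45), with 7 of 18 higher and 1 lower. Without the list members that lead or name the Treg-like clusters, a choice made after seeing the data, 15 of 16 tissue Treg genes (1.14), 9 of 10 Treg effector molecules (2.04) and 8 of 11 inhibitory receptors (1.30) were higher in the whole class, each list at percentile 100, while IL-2 and STAT5 signalling was at 0.49 (percentile 96.8) and TNF receptors at 0.04 (percentile 24.2) with 4 of 9 higher and 2 lower. Beside these groups, 8 of 13 mitochondrially encoded genes were lower in the tumor library in Treg-like cells (-0.76), and the epithelial markers Epcam (5.96-fold) and Krt18 (4.67-fold on 1 normal UMI), the members of the lung epithelium list that were measured, were higher.

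**Figure D3:**
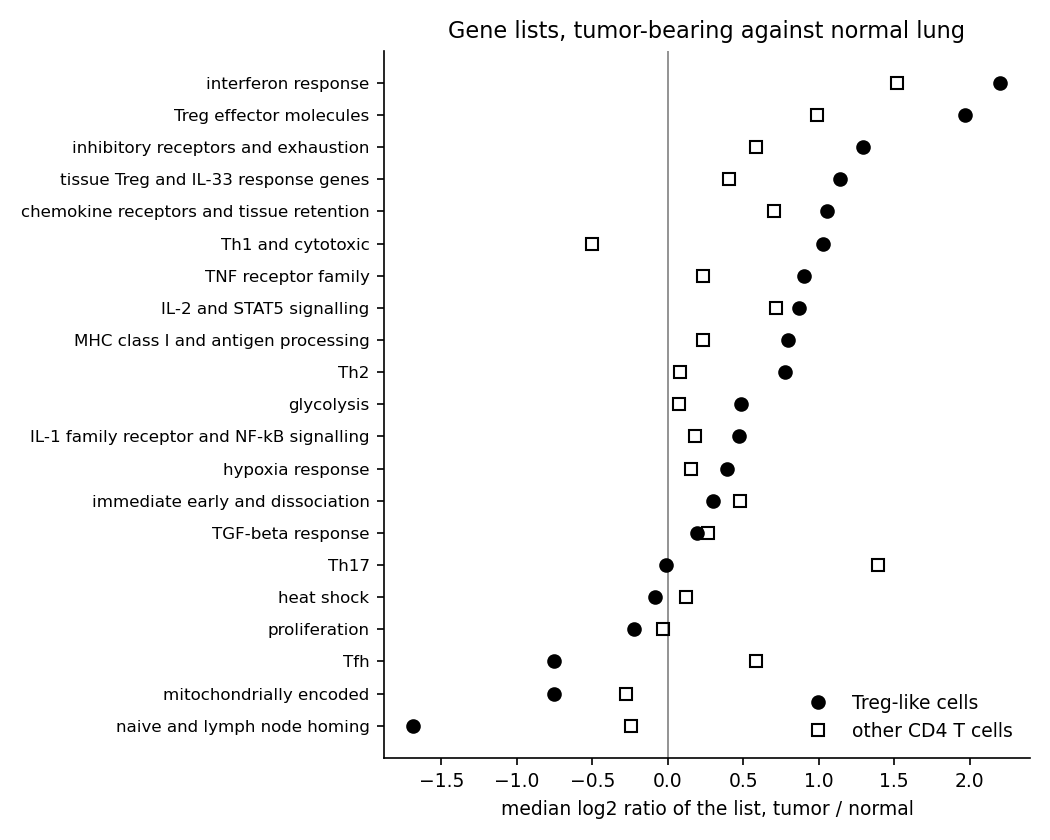
Median log2 ratio, tumor over normal, of each gene list in Treg-like cells (filled circles) and in the other CD4 T cells (open squares). The interferon response list lies at 2.20 and 1.52, and the naive and lymph node homing list at -1.68 and -0.24.

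In the remaining CD4 T cells, 18 of 21 interferon response genes and 8 of 10 Th17 genes were at least 1.5-fold higher in the tumor library, and S1pr5, Klrg1 and Gzma were higher in the normal library. Ifitm3, an antiviral membrane protein, was 25.2-fold higher in the tumor library (18.5 to 35.2), and Il22 and Il17a, cytokines of Th17 cells, were 19.4-fold (8.64 to 54.1) and 6.30-fold (4.26 to 9.62) higher. The Il17a UMIs were 177 from 31 tumor cells and 30 from 9 normal cells. Its interval treats UMIs of a cell as independent and is therefore too narrow. In the normal library S1pr5, a receptor that guides effector cells out of tissue, was 33.7-fold higher (11.2 to 166), Klrg1, a marker of terminal effector cells, 21.3-fold higher (12.5 to 39.3), and the protease gene Gzma 8.04-fold higher (6.78 to 9.60). The sums rested on 25281656 tumor and 27012911 normal UMIs.

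The rule further named Ifi204 at 63.6-fold (17.2 to 531, 2 UMIs in the normal library), Ifi211 at 39.3-fold, Mx1 at 18.3-fold and Ifit3b at 16.5-fold, which are interferon-induced, as well as Neb at 34.0-fold, Krt83 at 17.6-fold, Coro2a at 16.7-fold and Trnp1, with 112 UMIs against 0, at least 39.9-fold. Ifi204, Ifi211, Mx1, Ifit3b and Ifitm3 are leading genes of interferon-responding cluster 8, whose 74 tumor cells held 79.0%, 76.2%, 56.0%, 43.9% and 40.1% of their tumor UMIs. Without clusters 5 and 8, a choice made after seeing the data, their ratios were 12.8 (3.15 to 112), 12.8, 6.51, 15 and 14.4. On the side of the normal library it named Zeb2 (5.89-fold higher there), Ccl5 (5.27-fold, 5.02 to 5.55), Cx3cr1 (4.26-fold), Plek (3.98-fold), Slamf7 (2.96-fold), Hist1h1d (2.5-fold) and Anxa1 (2.37-fold). Zeb2 and Cx3cr1 are a transcription factor and a chemokine receptor of cytotoxic effector cells. The Klrg1 difference depended on the clustering, with log2 ratios of -0.89 with a Foxp3 UMI as the Treg-like criterion, -0.70 with each library clustered alone and 0.0023 at Leiden resolution 2, or -0.79 there without the cluster named proliferating.

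Preset genes of activation were higher in the tumor library here too, among them Tnfrsf9 (5.94-fold), Pdcd1 (4.58-fold), Il10 (3.74-fold), Gzmb (3.59-fold), Ccr8 (3.31-fold), Il2ra (2.97-fold), Lag3 (2.72-fold), Ctla4 (2.59-fold) and Foxp3 (2.35-fold, with a UMI in 1.30% and 0.630% of these cells). A Foxp3 UMI was seen in 14 of 621 tumor and 1 of 184 normal interferon-responding cells. Treg cells left in the non-Treg classes were not excluded as a source of these ratios. Of the 427 tumor UMIs of Gzmb, 206 came from 22 interferon-responding cells, and the log2 ratio without clusters 5 and 8 was 1.02. Havcr2 had a ratio of 2.14 on 10 against 5 UMIs (0.666 to 7.97) and Icos one of 1.03 (0.992 to 1.06), both not distinguishable from 1. Smaller differences were those of Tnfrsf4 (1.65-fold), Ikzf2 (1.47-fold), Tigit (1.36-fold), Tnfrsf18 (1.25-fold) and Areg (1.23-fold). Ifng, the Th1 cytokine, was 1.96-fold higher in the normal library (1.65 to 2.33), and Ccr7 1.5-fold, while Tcf7 and Gata3 had ratios of 0.984 and 0.949. Il1rl1 gave 15 against 14 UMIs, a ratio of 1.14 (0.515 to 2.56) that was not distinguishable from 1 at this depth.

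By list, 18 of 21 interferon response genes were higher in the tumor library in non-Treg cells (1.52, percentile 100) and 8 of 10 Th17 genes (1.40, percentile 100). Without clusters 5 and 8 the interferon list had 16 of 21 higher (0.92), and in naive-like cells alone 10 of 21 (0.55). Treg effector molecules had 9 of 14 higher (0.99), IL-2 and STAT5 signalling 7 of 12 (0.71), with the cytokine-signalling inhibitor Socs3 at 3.43-fold, chemokine receptors 8 of 15 with 1 lower (0.70), and inhibitory receptors 6 of 13 (0.58). The Th1 and cytotoxic list went the other way, with 7 of 14 lower and 4 higher (-0.50, percentile 0). In Th1 or cytotoxic-like cells alone its median was -1.56, with 8 of 14 lower and 2 higher. Of its genes in non-Treg cells, Gzma and Ccl5 were lower in the tumor library, while Gzmk (3.19-fold), Eomes (3.92-fold) and Gzmb were higher, the last by 1.39-fold (1.11 to 1.75) within Th1 or cytotoxic-like cells alone. Of 12 naive and homing genes 0 passed 1.5-fold in either direction (-0.24, percentile 0). Immediate early genes, which also answer to tissue digestion, had 9 of 21 higher and 0 lower (0.48, percentile 100).

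Since the series concerns IL-33 and its receptor ST2, the product of Il1rl1 (ENSMUSG00000026069, chromosome 1, 40404864 to 40465418, GRCm38.p6), this gene was followed by class. Over all CD4 T cells Il1rl1 was 5.54-fold higher in the tumor library (4.07 to 7.68), with 9.47 CPM (8.43 to 10.6) against 1.71 CPM (1.26 to 2.27). Treg-like cells supplied 285 of the 302 tumor UMIs (94.4%, 91.1 to 96.7) and 34 of the 48 normal UMIs (70.8%, 55.9 to 83.0). Within the Treg-like class the difference was not distinguishable from none at this depth, at 43.5 CPM (38.6 to 48.9) against 32.2 CPM (22.3 to 45.0), a ratio of 1.35 (0.944 to 1.99).

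An Il1rl1 UMI was seen in 174 of 1225 tumor Treg-like cells (14.2%, 12.3 to 16.3) and 19 of 249 normal ones (7.63%, 4.66 to 11.7), at median depths of 4672 and 3816 UMIs. After thinning, with 72 and 20 cells left out, the shares were 8.24% and 6.55%. Th1 or cytotoxic-like cells gave 14 cells (1.82%) and 10 cells (1.46%). Naive-like cells, taken as background, gave 1 of 4458 (0.0224%) and 0 of 5956, which allows up to 0.0504%, at median depths of 4099 and 3891 UMIs. Nearly all Treg-like signal came from activated cluster 0, where the tumor library had 47.9 CPM (42.5 to 53.8) against 88.6 CPM (61.0 to 124), a ratio of 0.541 (0.376 to 0.801), and resting cluster 10 had an Il1rl1 UMI in 0 of 144 and 1 of 184 cells. The class ratio depends on where the normal library's 65 activated cells are placed. At Leiden resolution 2, 62 of those 65 cells and 121 of the 1081 tumor cells joined a cluster named proliferating, which left 253 against 1 UMIs in Treg-like cells and a ratio of 33.3 with an interval from 5.93 to 1322. Leaving out the cells of that cluster gave 32.8. Removal of the top doublet scores, added after seeing the data, gave 30.5 with a like reassignment. It left 64 normal and 1015 tumor cells of cluster 0, of which 61 and 123 joined a cluster named proliferating on reclustering. Of the cells that joined at Leiden resolution 2, a Mki67 UMI was seen in 6 of 62 normal and 30 of 121 tumor cells. The leading genes of that cluster were S100a6, S100a4, Lgals3, Anxa2 and Lgals1 beside Pclaf, Birc5, Ccnb2, Ube2c and Mki67. Within cluster 0, 14 of 16 proliferation genes were lower in the tumor library by at least 1.5-fold (median log2 ratio -1.18). Whether these Il1rl1 ratios come from the removal of dividing cells therefore stays open.

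**Figure D4:**
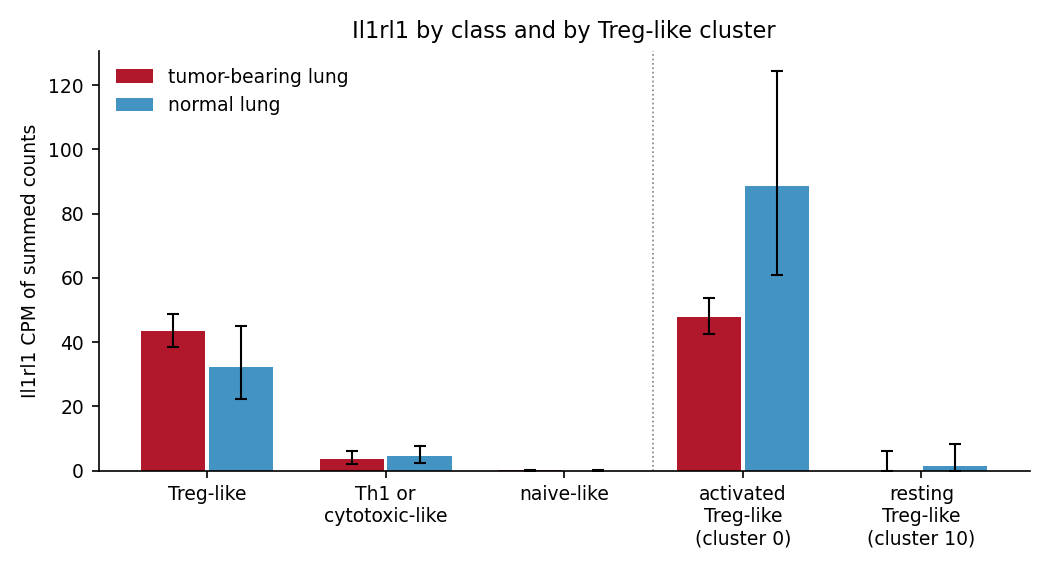
Il1rl1 CPM of summed counts by class and, right of the dotted line, within the activated and resting Treg-like clusters, with bars for each library and error bars for the exact Poisson 95% interval. Treg-like cells reach 43.5 CPM in the tumor library and 32.2 CPM in the normal library, and cluster 0 reaches 47.9 and 88.6 CPM.

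To see which transcripts accompany ST2, Treg-like cells with an Il1rl1 UMI were set against those without in each library, 174 against 1051 tumor cells and 19 against 230 normal cells. Il1rl1-positive cells had more Areg (1.72-fold in the tumor library and 5.65-fold in the normal library), more Klrg1 (1.76-fold and 33.8-fold) and more Nfkbiz, an NF-kB regulator (1.71-fold and 3.14-fold). The other genes higher in both were Rln3 (1.92-fold and 5.08-fold), Lmna (1.76-fold and 2.39-fold), Zc3h12a (1.60-fold and 1.86-fold), Cd83 (1.96-fold and 1.53-fold, the latter with an interval of 0.90 to 2.46), S100a4 (1.52-fold and 11.8-fold), Tagln2 (1.52-fold and 2.78-fold) and Gadd45b (1.5-fold and 2.20-fold). Lower in both were Tbc1d4 (ratios of 0.213 and 0.377), F2rl1, Plk2 (0.322 and 0.210), Nsg2 (0.347 and 0.0710) and Tubb2a (0.366 and 0.0197), where the normal library's intervals for Tbc1d4, F2rl1 and Plk2 included 1. Thinning before the split turned Tagln2 around in the tumor library (log2 ratio -0.080).

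Among preset genes Gata3, a transcription factor of Th2 cells and tissue Tregs, was 1.5-fold and 1.61-fold higher in Il1rl1-positive cells, Il2ra 1.61-fold and 1.10-fold, and Foxp3 1.13-fold and 1.27-fold, the normal library's intervals of the last 2 including 1. Ccr7 and Tcf7 were lower, at 0.672 and 0.675 in the tumor library and 0.104 and 0.0992 in the normal library. Gzmb was 1.35-fold and 49.8-fold higher, but thinning turned it around in the tumor library (-0.41). Icos had ratios of 0.998 and 4.21 and Tigit 0.889 and 5.23, but thinning turned Tigit around in the tumor library. By list, tissue Treg genes had a median log2 ratio of 0.43 in the tumor library and 1.90 in the normal library, both at percentile 100, with 5 of 17 and 10 of 11 genes at least 1.5-fold higher, and naive genes -0.57 and -2.03. The libraries disagreed on the Th1 and cytotoxic list, at -0.94 with 7 of 13 lower and 0 higher (percentile 0) in the tumor library against 1.31 with 4 of 6 higher (percentile 99.7) in the normal library, and on Treg effector molecules, at -0.06 with 1 of 15 higher and 3 lower against 1.65 with 10 of 12 higher. All 174 Il1rl1-positive cells of the tumor library, and all but 1 of those of the normal library, lay in cluster 0. Cells without a UMI included resting cluster 10 in both libraries. The split can therefore follow the 2 Treg-like clusters in both, and largely does in the normal library. Areg, Klrg1 and Cd83 are also leading genes of cluster 0. No values for this split within cluster 0 alone are given. A cell with 0 UMIs may still express the gene, and positive cells were deeper, with medians of 5204 against 4583 UMIs in the tumor library and 5038 against 3731 in the normal library.

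Clonal expansion, read from cells that share a receptor, asked how often Treg-like cells of each tissue come from the same ancestor. In the tumor library 296 of 962 Treg-like cells with a paired receptor (30.8%, 27.9 to 33.8) belonged to clonotypes of 2 or more cells, against 9 of 186 (4.84%, 2.24 to 8.99) in the normal library. In Th1 or cytotoxic-like cells the order was the opposite, 58 of 631 (9.19%, 7.05 to 11.7) against 96 of 534 (18.0%, 14.8 to 21.5), but 28 of the 96 were 1 clone. Without it, a choice made after seeing the data, the normal share was 68 of 506 (13.4%, 10.6 to 16.7), whose interval overlaps that of the tumor library, and expanded clonotypes were 29 of 602 and, with the clone counted, 29 of 467. Naive-like cells gave 0 of 3587, which allows up to 0.0836%, and 95 of 4591 (2.07%, 1.68 to 2.52), the latter in cells of low depth. Over all classes the shares were 363 of 5705 (6.36%, 5.74 to 7.03) and 201 of 5459 (3.68%, 3.20 to 4.22), the latter falling to 1.94% (1.59 to 2.34) when those 95 cells were not counted as expanded.

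Of the 296 expanded Treg-like cells of the tumor library 295 lay in activated cluster 0, 34.1% of its 864 cells (31.0 to 37.4), against 1.02% in resting cluster 10. A second cell of a clone is found more readily among more cells, and draws of 98 cells from each cluster, added after seeing the data, gave 7.61% (2.04 to 15.3 over draws) against 0, which allows up to 3.06%. The 9 of the normal library were split between 5 of 58 cells in cluster 0 (8.62%, 2.86 to 19.0) and 4 of 128 in cluster 10 (3.13%, 0.858 to 7.81), with overlapping intervals. With 58 cells from each, counting pairs within a cluster only, they gave 6.90% and 1.51% (0 to 6.90 over draws). The 7.61% of tumor cluster 0 came from a larger draw than the 6.90% of normal cluster 0. Expansion of activated cells was therefore not compared between the libraries at equal numbers. The drawn values show no excess among the tumor library's activated cells. Drawing 186 Treg-like cells from each library left 175 clonotypes on average in the tumor library and 182 in the normal library, with 10.9% and 4.30% of cells in expanded clonotypes and Shannon diversities of 7.42 and 7.5. Drawing 534 Th1 or cytotoxic-like cells left 512 and 467 clonotypes, the latter with the 28-cell clone. The largest Treg-like clonotype of the tumor library held 8 cells with TRAV12-2 and TRBV1, and the largest clonotype of the normal library held 28 Th1 or cytotoxic-like cells with TRAV9-1 and TRBV26. Left without cells under the thinning depth, added after seeing the data, expansion of naive-like cells in the normal library was 0.187%.

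**Figure D5:**
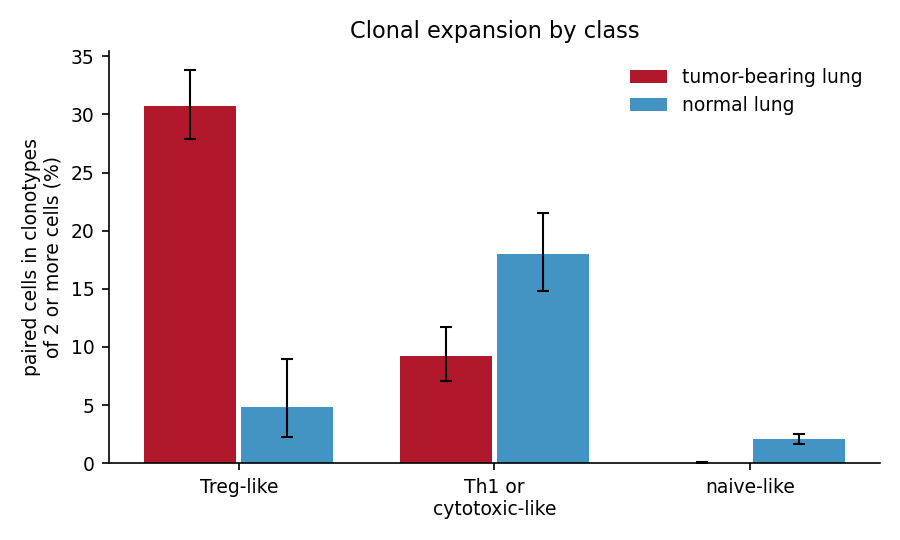
Share of cells with a paired receptor that belong to clonotypes of 2 or more cells (percent), by class and library, with bars for the share and error bars for the exact binomial 95% interval. Treg-like cells reach 30.8% in the tumor library and 4.84% in the normal library. These shares rest on 962 and 186 cells, and draws of 186 cells from each gave 10.9% and 4.30%.

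Whether Treg-like cells carry the receptors of other CD4 T cells was read from clonotypes found in both. Of 775 Treg-like clonotypes in the tumor library 1 was also seen in non-Treg cells, where shuffled class labels gave 48.6 on average (39 to 59). Of 182 in the normal library 1 was, where shuffling gave 6.21 (2 to 11). Of 108 clonotypes with 2 or more Treg-like cells in the tumor library 0 were shared, which allows up to 2.78%, and in the normal library 0 of 4. In each library the 1 shared clonotype held 1 Treg-like cell, so that with other cells counted toward expansion 1 of 109 and 1 of 5 were shared. No clonotype was seen in both libraries. With Treg-like cells taken as cells with a Foxp3 UMI the shared percentage in the tumor library was 2.86%, since Foxp3-negative cells of the Treg-like clusters then count as other cells.

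V gene usage differed by a few percentage points. TRBV19, a beta chain variable gene, was carried by 9.99% of paired tumor cells (9.22 to 10.8) and 7.60% of normal ones (6.91 to 8.34), a difference of 2.39 points. TRAV13D-2 was higher in the tumor library by 0.98 points, and TRAV6N-7, TRBV31 and TRBV26 differed by -1.26, -1.10 and -1.01 points. Among Treg-like cells of the tumor library TRBV19 was carried by 199 of 962 (20.7%, 18.2 to 23.4), and by 19.7% of clonotypes, against 7.29% of Th1 or cytotoxic-like and 7.81% of naive-like cells of that library and 4.84% of Treg-like cells of the normal library. Counted over clonotypes instead of cells, 3 of the 5 V genes remained among the 5 with the largest difference, while TRBV26 fell to -0.44 and TRAV13D-2 to 0.57 points. The 28-cell clone of the normal library carries TRBV26, and without it the TRBV26 difference was -0.52 points.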

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

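The tests on handling, on activated cells among naive-like ones (in the form given), on Il1rl1 and on independent rearrangements below were chosen only after the results they bear on were seen. Several genes and gene lists had tumor to normal ratios on opposite sides of 1 in Treg-like and in non-Treg cells. The difference between the classes was not tested, since there was 1 library per group. The log2 tumor to normal ratio was 5.13 in Treg-like and -2.40 in non-Treg cells for Ccl5, 2.16 and -2.09 for Cx3cr1, 1.03 and -3.01 for Gzma, 2.98 and -0.97 for Ifng, 2.22 and -4.41 for Klrg1, 2.16 and -1.99 for Plek, and 3.22 and -2.56 for Zeb2. Cx3cr1, Plek and Gzma had 0 UMIs in normal Treg-like cells, so that their Treg-like values are lower bounds, and Ifng and Zeb2 had 1. The contrast of Ifng was lost with the strict cell filter and at Leiden resolution 2, where its Treg-like value was -1.07 and -0.12. That of Klrg1 was lost at Leiden resolution 2, where its non-Treg value was 0.0023, and its Treg-like value is not read as a finding, since the gene defines cluster 0. The Tfh list had medians of -0.76 and 0.58, and the Th1 and cytotoxic list 1.03 and -0.50. The Th17 list (-0.02 and 1.40) and the heat shock list (-0.09 and 0.12) also had medians of opposite sign. Their Treg-like medians each include 2 genes with 0 normal UMIs, entered at their floor.

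Il1rl1 was 5.54-fold higher in the tumor library over all cells and 1.35-fold higher (0.944 to 1.99) per Treg-like UMI. The ratio within activated cluster 0 was lower, 0.541 (0.376 to 0.801), and a candidate explanation for the class ratio lying above it is the larger part of tumor Treg-like cells in that cluster, since normal Treg-like cells weighted to the tumor library's mix would have 80.7 CPM against their measured 32.2 and the tumor library's 43.5. That mix raises the class ratio and so does not account for its being small, and the ratio within cluster 0 has no explanation tested here. Free Il1rl1 RNA in the suspension is argued against, since 0.0224% of the tumor library's naive-like cells had a UMI against 14.2% of its Treg-like cells. It stays open whether the 65 normal cells of cluster 0 are the same cell type as the 1081 tumor cells, and the tissue difference itself was not tested against a batch difference.

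Immediate early genes, which T cells switch on within minutes of stimulation or of tissue digestion, had a median log2 ratio of 0.58 in naive-like cells, with Egr1 at 2.32-fold and Nr4a1 at 1.79-fold. The median was 0.49 after thinning, where random lists reached 0.09 at the upper bound. Thinning leaves a gene's expected part of a summed count unchanged and acts only through the cells left out. This value therefore cannot decide whether a depth difference plays a role. Activated cells left in the class are argued against as the whole source, as 2685 tumor and 4303 normal naive-like cells with a Ccr7 UMI and none of 8 activation genes still gave 0.49. Handling or library batch and a response to the tumor-bearing lung cannot be told apart with 1 library per group.

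In the normal library 94 naive-like cells in 45 clonotypes shared a receptor, while the tumor library had 0 such pairs where its cell number predicted 32.4. These cells had 0.467 times the UMIs of the other naive-like cells (0.440 to 0.494, medians 1855 and 3971.5), which fits a candidate explanation that the RNA of 1 cell was read under 2 barcodes, and 54.7% of such pairs lay in 1 cluster against 26.8% of random pairs. Independent rearrangements are argued against, since 0 pairs of naive-like cells shared a receptor across the libraries where that rate gives 82.8 (62.1 to 108). Whether they are sister cells of recent thymic output stays open, as Sox4, high in thymocytes, had a ratio of 0.515 with an interval of 0.106 to 1.51 on 3 UMIs. The barcodes of such a pair differed at 8 or more positions, so single sequencing errors in a barcode do not account for them.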

How the results depend on the processing

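Of the values that answer a comparison, 228 moved by no more than their interval or the limit set for counts, and 64 moved further. For list medians that interval came from the spread of the list's genes and not from counting error. Of the values of single genes, V genes and further lists 1115 stayed, 263 moved and 10 turned around. The Treg-like share lay between 13.9% and 18.0% in the tumor library and between 2.54% and 3.55% in the normal library, and expansion of Treg-like cells between 10.9% and 36.2% against 3.93% and 5.96%, the lowest tumor value from equal draws. The tissue Treg list in Treg-like cells had medians from 0.42 to 2.69, the lowest within cluster 0 alone, and the interferon list from 2.05 to 2.69. In non-Treg cells the Th17 list lay between 1.32 and 1.5 and the Th1 and cytotoxic list between -0.56 and -0.12. No paired analysis was possible because the groups share only replicate number 1 and the results come from no test. Where a construction is not named below, the cause was not tested. Depth limits what rests on the 249 normal Treg-like cells and genes with 1 to 3 UMIs.

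Without a cell filter, and with the strict filter, doublets kept or differing genes left out, the effector-like cells separate into Th17-like and Th1 or cytotoxic-like clusters and are counted together. Without a cell filter the tumor shares of effector-like and naive-like cells were 11.7% and 60.3%, with the strict filter the naive-like share was 60.6%, and with doublets kept the effector-like share was 11.8%. At Leiden 0.5 they were 11.6% and 65.9%, with 85.6% naive-like in the normal library. At Leiden 2, where a cluster named proliferating takes cells of the activated Treg-like cluster, Treg-like shares were 14.5% and 2.61%, effector-like 6.83% and 5.87%, naive-like 64.3% and 88.2%, 9 of 20 Treg-like named genes were kept, the naive and homing median was -2.07, the Il1rl1 ratio 33.3, and Treg-like cells held 83.8% and 2.08% of Il1rl1 UMIs. With each library clustered alone, the tumor Treg-like share was 13.9%, the normal naive-like share 78.6%, the naive and homing median -2.28 and the tumor Il1rl1 part 90.4%. With a Foxp3 UMI as the criterion, Treg-like shares were 16.1% and 2.91%, the tumor Il1rl1 part 88.4% and the shared clonotypes 2.86%, since Foxp3-negative cells of Treg-like clusters then count as non-Treg. Leaving out the cells of that proliferating cluster of Leiden 2, where a Mki67 UMI was seen in 33 of 132 tumor and 10 of 72 normal cells, gave 10 of 20 named genes, a naive and homing median of -2.07, an Il1rl1 ratio of 32.8 and a normal Il1rl1 part of 6.67%.

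Thinning before summing kept 11 of 20 named genes in Treg-like and 9 in non-Treg cells, a minimum of 300 UMIs kept 12 and 8, and a minimum of 30 UMIs kept 13 in non-Treg cells, by construction of the rule. Median of ratios scaling left 19 lists in Treg-like and 21 in non-Treg cells with a median above 0, as with total counts. By beta chain alone, which merges cells with different alpha chains, expansion was 36.2% in tumor Treg-like cells, 0.446% and 3.44% in naive-like cells and 7.73% and 5.11% over all classes. Over clonotypes 3 of 5 V genes were kept.

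Some alternatives were chosen after seeing the data. Removing the top doublet scores gave Treg-like shares of 15.8% and 2.54%, naive-like 57.3% and 82.8%, 9 of 20 Treg-like named genes, a naive and homing median of -2.29, an Il1rl1 ratio of 30.5 and Il1rl1 parts of 86.0% and 2.08%. There 61 of the 64 normal cells left from cluster 0 joined a cluster named proliferating, much as at Leiden 2. Clustering without differing genes gave naive-like shares of 68.8% and 86.6%. Without cells under the thinning depth, expansion was 0.187% in normal naive-like cells and 1.91% over all classes of the normal library. In draws of 186 cells from each library, expansion of Treg-like cells was 10.9% and 4.30%. Fewer cells leave fewer pairs in the tumor library. The normal library has just 186 such cells, and its value differs since only pairs within the class count in the draws. In draws of 3587, expansion of normal naive-like cells was 1.64%. Without naive-like cells, which leaves fewer cells in the total, it was 17.1% and 12.2% over all other classes. Within cluster 0 alone 8 of 20 named genes were kept, the tissue Treg median was 0.42, the naive and homing median -1.05 and the Il1rl1 ratio 0.541. Without the largest clone expansion of normal Th1-like cells was 13.4%. Without clusters 5 and 8 the interferon median in non-Treg cells was 0.92.

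A gene's value counted as turned around if its interval excluded no difference and it then changed sides. The values that turned around were the log2 ratios of Areg (-0.34), Icos (-0.34) and Tubb2a (0.28) within cluster 0 alone, the log2 ratio of Ifng in Treg-like cells (-1.07 with the strict filter, -0.12 at Leiden 2), of Klrg1 in non-Treg cells (0.0023 at Leiden 2), and, with thinning before the split on Il1rl1 in the tumor library, of Gzmb (-0.41), Tagln2 (-0.080), Tigit (0.12) and Tnfrsf4 (-0.052). Values not counted by that rule also changed sides within cluster 0. Examples are the Il1rl1 ratio, from 1.35 to 0.541, and the Th2 list median, from 0.78 to -0.32.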

Other observations

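The test on shared beta chains, the values within cluster 0 and the values without the largest clone were chosen only after the results they bear on were seen. Within activated cluster 0 proliferation genes were lower in the tumor library, 14 of 16 by at least 1.5-fold (median log2 ratio -1.18, percentile 0), while IL-2 and STAT5 signalling was higher (0.96, percentile 100). Of the cells of cluster 0, 62 of 65 normal and 121 of 1081 tumor cells joined the cluster named proliferating at Leiden resolution 2. The difference can therefore follow which normal cells cluster 0 holds. Over the whole Treg-like class 3 of 16 proliferation genes were higher and 6 lower (-0.22). When genes that differed between the libraries were left out of the clustering, the Th1 or cytotoxic-like class separated into a cluster led by Tmem176b, Tmem176a, Cxcr6 and Cxcr3, with 781 tumor and 558 normal cells, and a cluster led by Gzma, Ccl5, Nkg7, Cx3cr1 and S1pr5, with 42 tumor and 132 normal cells.

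Gzma, Ccl5, Zeb2, Cx3cr1, S1pr5 and Klrg1 stayed higher in the normal library's Th1 or cytotoxic-like cells without its largest clone. That clone of 28 cells gave 5.99% of the Gzma UMIs of the Th1 or cytotoxic-like class, 14.8% of Ccl5, 17.9% of Zeb2, 28.3% of Cx3cr1, 30.8% of S1pr5 and 41.2% of Klrg1. Without it the normal to tumor ratios within the class were 17.8 for Gzma, 7.53 for Ccl5, 6.90 for Zeb2, 8.97 for Cx3cr1, 31.3 for S1pr5 and 29.7 for Klrg1. The value for Klrg1 hangs on the clustering, since over non-Treg cells its normal to tumor ratio was 0.998 at Leiden resolution 2.

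Other lists gave these medians of the log2 tumor to normal ratio in Treg-like and in non-Treg cells. Mitochondrially encoded genes were at -0.76 and -0.27, glycolysis at 0.49 and 0.07, hypoxia at 0.39 and 0.15, TGF-beta response at 0.19 and 0.27, heat shock at -0.09 and 0.12, and immediate early genes at 0.30 and 0.48. Th2 genes were at 0.78 and 0.08, though at -0.32 within cluster 0 with 0 of 6 higher and 1 lower, Th17 genes in Treg-like cells at -0.02, proliferation genes in non-Treg cells at -0.03, and in non-Treg cells tissue Treg genes at 0.40, TNF receptors at 0.24, MHC class I at 0.23 and IL-1 family and NF-kB signalling at 0.18. In Treg-like cells the Th17, Th1 and cytotoxic, hypoxia and heat shock medians include 2, 3, 1 and 2 genes with 0 normal UMIs, which enter at their floor. Within cluster 0 the Th17 median was -1.26 with 3 of 7 genes at that floor, so no direction is read from it. Background lists held few measured genes. The lung epithelium list had 2 in Treg-like cells (2.40), Epcam at 5.96-fold and Krt18 at 4.67-fold on 1 normal UMI, and 3 in non-Treg cells (1.55), where Scgb1a1, an airway secretory protein, went the other way at a ratio of 0.134. The myeloid list was at 0.80 and 0.10 and the B cell list at 0.68 and 0.22 (0.03 within cluster 0), erythroid genes had 0 measured members, and the sex check had 1, at 0.46 and 0.06. The unnamed cluster 11 held 58 tumor and 8 normal cells with median depths of 1058 and 822.5 UMIs.

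A hypothesis was that different Treg-like cells of the tumor library were selected for like receptors. Of 739 distinct beta chain nucleotide sequences in its Treg-like cells, 60 (8.12%) shared the TRBV gene and CDR3 amino acids with another, where draws of as many beta chains from naive-like cells of that library, matched on TRBV gene, gave 2.18 on average (0 to 6) and 10 at most. A first count over clonotypes, 118 of 775 against 2.86 (upper bound 8), had counted cells with 1 beta chain and several alpha chains as different, so it was replaced. Of the 60, 34 used TRBV19, and the sequences included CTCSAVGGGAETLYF with TRBV1, from 5 nucleotide sequences in 7 Treg-like cells, and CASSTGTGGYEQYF with TRBV19, from 4 in 5 cells, neither seen in other cells. An excess over every draw was also seen in normal Th1 or cytotoxic-like cells, with 10 of 463 against 0.82 on average (0 to 4) and 6 at most, while tumor ones gave 6 of 601 against 1.48 (0 to 6) and 12 at most, and normal Treg-like cells 0 of 182. The excess in tumor Treg-like cells is consistent with selection by shared antigens, but errors in chain assembly within a clone were not tested, and the count was found and tested on the same cells.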
